A study of Homo sapiens with 8 samples.

How the data were processed

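RNA sequencing was done on 8 libraries of the human leukaemia line MV4-11, 4 from control cells and 4 from CD36 knockout cells made with CRISPR-Cas9. Per the labels' protocols, RNA was extracted with Trizol and libraries were made with an Illumina TruSeq RNA kit. The submitters' processing notes name CASAVA 1.8, Trimmomatic, FastQC, HISAT2, StringTie, edgeR and the genome build GRCh38, without saying which step used which tool. The counting tool, the annotation release, strand and filters are not given in the sources used here. A gene and its antisense or overlapping partner could therefore share reads.

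The authors deposited 1 table with whole-number counts per gene for each library, not normalized, per the file headers and the values. It lists 59064 loci, of which 58676 have an Ensembl gene identifier and 388 are loci assembled by the authors without a name or position in the table. The same table holds the authors' deposited FPKM values, which within each library equal the count divided by gene length and by the total of the count column. Counts summed to between 14610067 and 17824940 per library, and every locus was included in library sizes, unnamed ones too (0.274% to 0.732% of counts). A single count in the shallowest library equals 0.068 CPM. This floor covers counting error only. The number of per-sample columns left unused was 0. Groups came from the genotype in the labels, and no library was left out of the main comparison.

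Counts were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr, TMM normalization, robust dispersion estimates and a robust quasi-likelihood fit with group as the single term, then Benjamini-Hochberg adjustment over the 17192 genes kept, 284 of them unnamed loci. Genes with adjusted p under 0.05 are called higher or lower. Values in CPM are TMM-normalized, given as mean ± SD over 4 libraries, and SE is that of the log2 fold change from the fit. CD36 was also compared by a two-sided exact permutation test. Gene positions came from GENCODE release 29 on GRCh38 and were found for 98.3% of the tested genes. That release may differ from the one the authors counted with, so overlaps between genes are those of release 29.

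The 39 gene lists, the test, the alternatives and the rule for named genes were fixed before the data were examined. Lists with at least 5 tested genes, 37 in all, were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were run beside it. Of the 8 lists called, 2 (MHC class II, and the unfolded protein response and ATF4 targets) hold with an estimated correlation. Fry, which asks whether the genes of a list move one way on balance and compares them with no other genes, called 28. Counts of members higher or lower are over all genes tested. Adjusted over the list alone, they differed by 1 gene in 7 lists: MHC class II then had 12 higher, NF-kB 3 higher, monocyte and macrophage markers 14 higher, ribosomal proteins 31 lower, BCL2 family and caspases 10 lower, adhesion and migration 13 lower, and scavenger receptors 5 lower. CD36 is in no list.

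Genes were named by a rule: CD36, the 10 largest rises and 10 largest falls among genes with adjusted p under 0.05, a mean of at least 2 CPM, non-overlapping groups and a symbol that is not a clone, antisense or pseudogene name, then up to 4 members per list with the smallest adjusted p. Members are named for the 16 lists described in the report with examples, a choice of lists made after it was seen which passed; the rule allowed members of lists that failed their test to be left out. The values of 1 gene named by this rule are not reported here. HLA-E, HLA-DQA1, CIITA and members listed only by name are given in addition, and were chosen after their values were seen.

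After the first results were seen, genes with a mean of at least 5 CPM were placed in 10 Mb windows, and each window with at least 10 genes was compared with 10000 random draws of as many genes. For a regional offset, the knockout libraries of each gene were offset by the median log2 fold change of the other genes in its window and the fit was repeated. Those other genes could include members of the same list.

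On simulated counts drawn from the means and library sizes of the knockout and control libraries, with 200 of 16913 genes changed, the test recovered 26% of the genes changed by a log2 fold change of 0.25, 74% at 0.5, 82% at 1 and 96% at 2, with 7 false calls. It called 10 of 10 changed lists and 0 of 30 unchanged lists, and the 1 shifted window with 0 others of 284. Simulated genes varied independently, lists were drawn at random with all members of a changed list shifted alike, and all other genes were left unchanged. In the data 52.7% of the tested genes passed, and list members can be correlated (estimated at 0.46 for ribosomal proteins). The simulation therefore does not give the rate of false list or window calls in these data.

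Within each group, every pair of replicates differed by more than sampling noise: the median chi-square per gene was 1.60 to 2.52 times that of Poisson counts, over genes with at least 20 counts in the pair. The mean chi-square per gene was 11.4 to 12.7 in pairs with knockout replicate 2, against 2.01 to 6.46 in the other pairs. Some genes of that library therefore departed more strongly than the median shows. No 2 libraries were identical.

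Alternatives were DESeq2 size factors in edgeR, library size alone, no filter beyond a total above 0, at least 1 CPM in 4 libraries, DESeq2 1.42.0, limma-voom, limma-trend on log2(FPKM + 1) and on log2(FPKM + 0.1) for genes with a mean of at least 1 FPKM, a replicate block, mitochondrial genes left out, and each library left out in turn. The regional offset, the unnamed loci left out, 5 Mb windows and windows of genes with at least 20 CPM were added after the data were seen.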

Results

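Gene expression was measured by RNA sequencing in MV4-11 cells, a human acute myeloid leukaemia line that carries an MLL fusion. The series held 4 libraries from control cells and 4 libraries from cells in which CD36 had been knocked out with CRISPR-Cas9. CD36 is a membrane receptor that takes up long-chain fatty acids and oxidised lipoproteins. The comparison asks which transcripts differ between MV4-11 cells with and without CD36. Total counts per library ranged from 14610067 to 17824940, and between 28136 and 28999 genes had at least 1 count. A single count in the shallowest library corresponded to 0.068 CPM, the unit of counts scaled to library size used throughout. The labels do not say whether replicates came from separate cultures, nor whether the knockout cells were 1 clone or a pool, so p-values measure the spread between these libraries, which may be technical.

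CD36 transcript was lower in all 4 knockout libraries than in all 4 controls. CD36 (ENSG00000135218, chromosome 7, 80369575 to 80679277, GRCh38) stood at 61.2 ± 3.05 CPM (SD, n = 4) in control cells and at 8.48 ± 1.03 CPM (SD, n = 4) in knockout cells, so 13.9% of the control level remained. Raw CD36 counts were 963, 912, 991 and 1058 in the control replicates and 152, 142, 114 and 142 in the knockout replicates. The log2 fold change was -2.85 ± 0.07 (SE), a 7.23-fold lower level, with adjusted p = 2.4e-28 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. A two-sided exact permutation test of the CPM values gave p = 0.029, the smallest value that 4 against 4 libraries can reach. On log2(FPKM + 1) values, a scale that understates the change of low genes, the difference was -1.90. The count covers the whole locus, and the overlapping gene AC073850.1 was counted separately, so reads shared between them cannot be assigned.

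More than 1 in 2 of the tested genes differed between the groups, mostly by small amounts. Of 17192 genes tested, 9059 (52.7%) had an adjusted p under 0.05 by edgeR, 4480 higher and 4579 lower in the knockout. The median size of the change among these genes was 0.43 on the log2 scale. A change of at least 2-fold was seen for 1279 of them, 520 higher and 759 lower. For 8031 genes (46.7%) the 4 knockout libraries lay entirely on one side of the 4 control libraries, against 2.86% by chance. The spread between replicates was small, with a common biological coefficient of variation of 6.63%. The count of genes past the threshold by at least 2-fold was 2015 with no filter on low counts. With limma-trend, which changed the test, the unit and the genes tested together, it was 385 on log2(FPKM + 1) values and 685 on log2(FPKM + 0.1) values of 14595 genes.

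The genes with the largest rises included genes barely transcribed in control cells. IGSF10 (ENSG00000152580, chromosome 3, 151425384 to 151458709), an immunoglobulin superfamily member, rose from 6.21 ± 1.05 to 129.98 ± 7.14 CPM (SD, n = 4), and DNAJC5B (ENSG00000147570, chromosome 8, 66021560 to 66100526), a J-domain protein gene, rose from 30.6 ± 1.11 to 294.4 ± 6.28 CPM. SSC4D, which encodes a scavenger receptor cysteine-rich protein, rose from 3.63 ± 0.53 to 77.3 ± 4.73 CPM. MAGEA4, a cancer-testis antigen gene, rose from 3.38 ± 0.35 to 33.7 ± 1.10 CPM. The transcription factor gene TBX4 (log2 fold change 4.66), FAM163A (4.20), the translation termination factor gene GSPT2 (3.40), EMP2 (3.26) and the progesterone receptor gene PGR (2.93) were each below 1 CPM on average in control cells. COL4A2, a type IV collagen chain gene, rose by 3.55 ± 0.59 (SE) with 25 counts over the 4 controls, of which 17 were in control replicate 2, and gene COL4A2 stood at 4.74 without that library. TBX4 and FAM163A lie in raised windows. IGSF10, SSC4D and COL4A2 overlap the tested genes MED12L, ZP3 and COL4A1, and without known strand their reads cannot be fully separated.

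Among the largest falls, several genes were reduced to a few counts. IGF2BP1 (ENSG00000159217, chromosome 17, 48997412 to 49055650), which encodes an RNA-binding protein, fell from 60.5 ± 3.12 to 0.093 ± 0.112 CPM (SD, n = 4), or from 3881 counts to 6 summed over the 4 libraries. Its relative IGF2BP3 fell from 4.24 ± 0.47 to 0.24 ± 0.12 CPM. The transcription factor gene DMRTA2 fell from 54.4 ± 2.25 to 0.60 ± 0.33 CPM, the ubiquitin ligase gene TRIM32 from 6.96 ± 1.00 to 0.098 ± 0.122 CPM, and PPP1R3A, a glycogen-targeting phosphatase subunit gene, from 17.5 ± 1.28 to 0.25 ± 0.18 CPM. KIT (ENSG00000157404, chromosome 4, 54657918 to 54740715), the stem cell factor receptor, fell from 49.4 ± 1.66 to 1.82 ± 0.41 CPM, a log2 fold change of -4.75 ± 0.10 (SE) with adjusted p = 9.3e-31 by edgeR. OLFML3 (-4.16), the secreted glycoprotein gene STC2 (-4.05), the lipase inhibitor gene G0S2 (-3.88) and the lactoperoxidase gene LPO (-3.61) completed the 10 largest falls. The fitted changes of the genes near 0 counts rest on few reads and on the scale: gene IGF2BP1 was at -9.24 in edgeR, at -10.30 without knockout replicate 3 and at -2.92 on log2(FPKM + 1) values, and gene TRIM32 was at -6.12 and at -7.20 without knockout replicate 2. IGF2BP1, LPO, G0S2 and STC2 lie in raised windows and PPP1R3A and OLFML3 in lowered ones, and TRIM32 lies inside ASTN2, while IGF2BP3 and LPO overlap MALSU1 and MKS1.

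**Figure D1:**
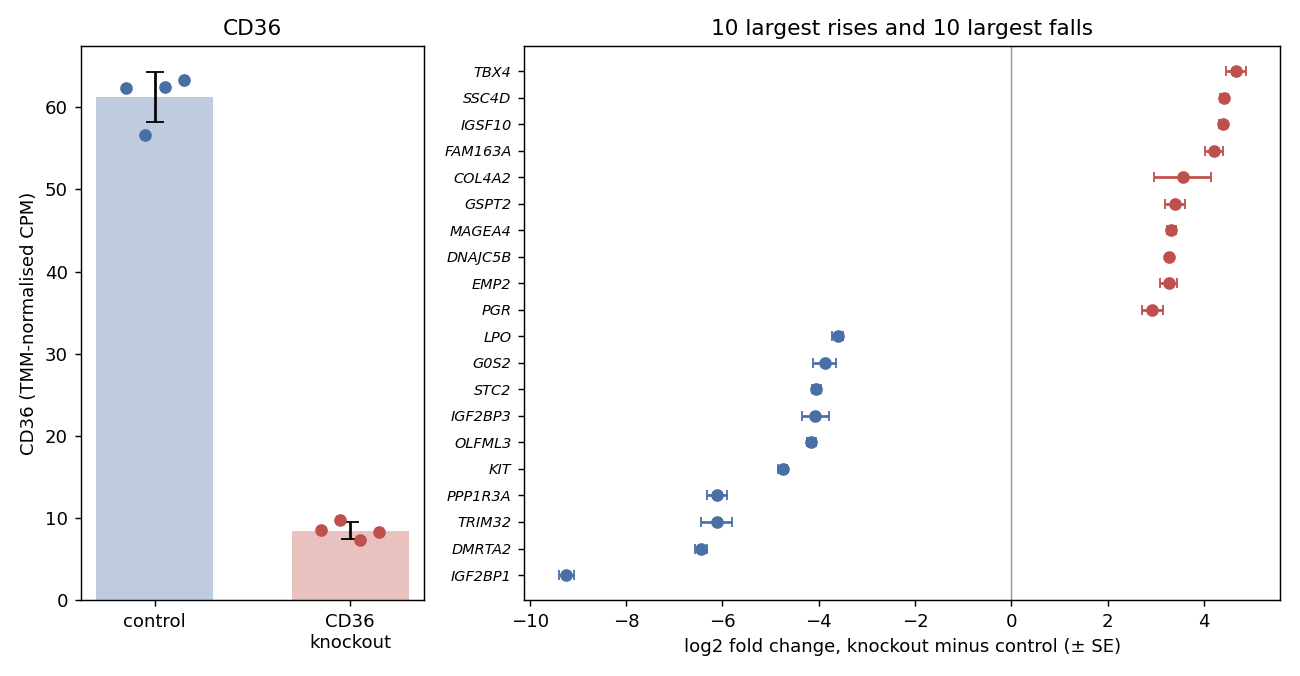
Left, CD36 level in TMM-normalised CPM in each library (points), with the group mean (bars) and SD (error bars), n = 4 per group; control libraries lie at 56.7 CPM or above and knockout libraries at 9.80 CPM or below. Right, log2 fold change (knockout minus control) and SE of the 10 genes with the largest rise (red) and the 10 with the largest fall (blue), from TBX4 at 4.66 to IGF2BP1 at -9.24.

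Changes were not spread evenly over the genome: long stretches of neighbouring genes moved together. In 32 of 284 windows of 10 Mb the median log2 fold change was higher than in random draws of the same number of expressed genes, and in 20 it was lower (adjusted p under 0.05, 10000 random draws). On chromosome 17 from 20 to 90 Mb, 90.1% of 523 expressed genes had a log2 fold change above 0, with a median of 0.47. On chromosome 1 from 140 to 220 Mb, 90.2% of 386 genes did, with a median of 0.42. Chromosome 5 from 50 to 100 Mb (median 0.38, 132 genes), chromosome 7 from 130 to 160 Mb (0.51, 106 genes), chromosome 6 from 30 to 60 Mb (0.31, 215 genes) and chromosome 9 from 130 to 140 Mb (0.39, 89 genes) were also higher. The deepest fall was on chromosome 12, where all 30 expressed genes between 20 and 30 Mb were lower, with a median of -1.45, and the 15 genes between 30 and 40 Mb had a median of -0.71. Genes in the higher windows passed the edgeR test as higher in 75.8% of 1683 cases, against 25.9% of the genes outside shifted windows. The windows were chosen by these same changes, so a larger share follows from that choice and is no separate evidence. Because neighbouring genes moved together, every gene group below was also tested after an offset by the median change of the other genes in each gene's own window.

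**Figure D2:**
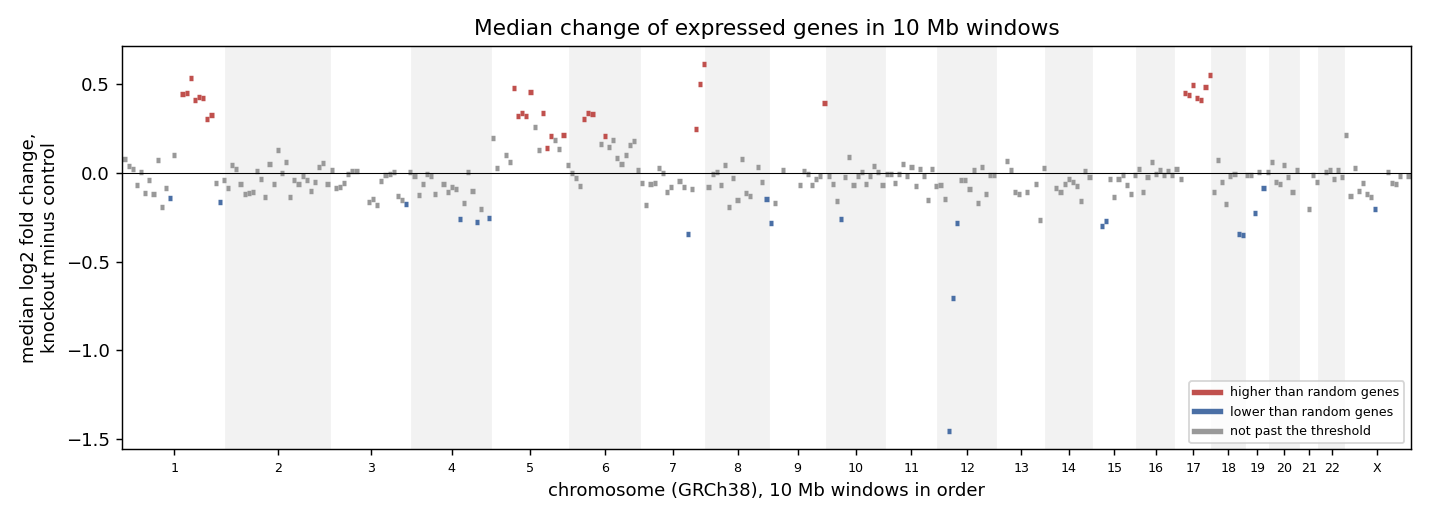
Median log2 fold change (knockout minus control, vertical axis) of expressed genes in each 10 Mb window along chromosomes 1 to 22 and X (horizontal axis), with windows past the threshold in red (32 higher) or blue (20 lower). Runs of raised windows lie on chromosomes 1, 5, 6, 7 and 17, and the lowest window, at -1.45, is on chromosome 12.

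MHC class II genes, which encode the molecules that present peptides to CD4 T cells, rose together. Of 12 tested members 11 were higher, with a median log2 fold change of 1.15 (camera adjusted p = 4.9e-07, and adjusted p = 0.027 with an estimated correlation). HLA-DQA1 (log2 fold change 0.51, edgeR adjusted p = 0.073) did not pass. HLA-DRA (ENSG00000204287, chromosome 6, 32439842 to 32445046) rose from 3.03 ± 0.61 to 17.6 ± 2.005 CPM (SD, n = 4), HLA-DRB1 from 46.1 ± 0.89 to 124.5 ± 4.70 CPM, HLA-DRB5 from 10.7 ± 0.79 to 47.2 ± 2.67 CPM and HLA-DPA1 from 1.61 ± 0.04 to 7.46 ± 0.75 CPM. CIITA, the transactivator of these genes, lies on another chromosome and rose by 1.30 ± 0.12 (SE) on the log2 scale. Of the 12 members 10 lie in shifted windows, all of them HLA genes in the raised part of chromosome 6. With the regional offset the median was 0.91, with 8 members higher and adjusted p = 2.2e-06. HLA-DRB1 and HLA-DRB5 are near-identical, so their separate values are uncertain.

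MHC class I and antigen processing genes also rose as a group, but part of that rise was shared with their chromosome neighbours. Of 14 tested members 13 were higher, and HLA-E was lower at -0.42 ± 0.04 (SE). The median was 0.36 (camera adjusted p = 0.00014, and adjusted p = 0.26 with an estimated correlation). The peptide transporter gene TAP1 rose from 54.0 ± 1.44 to 110.4 ± 7.14 CPM, the immunoproteasome gene PSMB9 from 28.6 ± 2.82 to 58.6 ± 4.62 CPM, the aminopeptidase gene ERAP1 from 111.3 ± 5.24 to 173.7 ± 5.32 CPM and B2M, the invariant light chain, from 944.9 ± 9.02 to 1284 ± 36.2 CPM (SD, n = 4). TAP1 and PSMB9 overlap each other. Of the 14 members 10 lie in shifted windows, and with the regional offset the median was 0.18 and the call ended (adjusted p = 0.059). The other genes of a window included members of this list and MHC class II genes, so the offset can remove part of the list's own rise.

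Genes of cholesterol synthesis and LDL uptake rose. Of 23 tested members 18 were higher and 2, SREBF2 and TM7SF2, were lower, with a median of 0.45 (camera adjusted p = 5.7e-07, and adjusted p = 0.060 with an estimated correlation). HMGCS1 rose from 135.6 ± 5.62 to 225.9 ± 6.85 CPM (SD, n = 4), ACAT2 from 58.7 ± 1.30 to 109.5 ± 6.76 CPM and INSIG1, a sterol-regulated membrane protein gene, from 146.1 ± 2.19 to 328.7 ± 2.82 CPM. INSIG1 lies in the raised end of chromosome 7, and its log2 fold change of 1.17 was 0.58 with the regional offset. For the list, the offset left a median of 0.40 (adjusted p = 1.8e-06).

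Fatty acid and lipid droplet lists did not stand apart from other genes by camera. Fry, which compares a list with no other genes, called uptake and oxidation lower (adjusted p = 0.034 and 0.0062) and synthesis and lipid droplets higher (adjusted p = 0.00031 and 0.00067). In the list for fatty acid uptake and activation, 5 of 15 tested members were higher and 6 lower (median -0.11, camera adjusted p = 0.77). CAV1 rose from 6.94 ± 0.57 to 18.3 ± 1.14 CPM (SD, n = 4) and DBI from 74.9 ± 5.14 to 97.5 ± 5.61 CPM, while the acyl-CoA synthetase gene ACSL1 fell from 63.5 ± 1.998 to 45.8 ± 2.39 CPM and the lipoprotein receptor gene VLDLR from 168.9 ± 5.00 to 105.2 ± 2.09 CPM. In the oxidation list, 4 of 22 members were higher and 9 lower (median -0.07, adjusted p = 0.40), with HSD17B4 higher by 0.43 and ECI1, HADH and ETFDH lower by -0.56, -0.36 and -0.44 on the log2 scale. In the list fatty acid synthesis and desaturation, 8 of 16 were higher and 3 lower (median 0.08, adjusted p = 0.35, against 0.041 with DESeq2), among them ACLY, which makes cytosolic acetyl-CoA, at 0.73 and the regulator gene SREBF1 at -0.42. With the regional offset 4 members of this list were higher and 5 lower, with a median of -0.03. ACLY lies in the raised part of chromosome 17, where the other genes of its window had a median of 0.49. Of 17 lipid droplet and triglyceride genes 4 were higher and 3 lower (median 0.01, mean -0.17, adjusted p = 0.71), with G0S2 lowest and the sterol esterification gene SOAT1 (0.90) and AGPAT2 (0.92) highest among the named members. Both SOAT1 and AGPAT2 lie in raised windows, with neighbours at 0.41 and 0.38. ACSL1, VLDLR and ETFDH lie in lowered windows, with neighbours at -0.24, -0.27 and -0.26, against their own changes of -0.47, -0.68 and -0.44. CAV1, which rose, also lies in a lowered window, with neighbours at -0.36.

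Unfolded protein response and ATF4 target genes fell. Of 30 tested members 22 were lower and 6 higher, with a median of -0.73 (camera adjusted p = 4.1e-09, and adjusted p = 0.027 with an estimated correlation). PSAT1, an enzyme of serine synthesis, fell from 480.5 ± 6.98 to 112.4 ± 3.59 CPM (SD, n = 4), the amino acid transporter gene SLC7A5 from 354.3 ± 11.4 to 110.2 ± 4.53 CPM, the glutathione-degrading enzyme gene CHAC1 from 43.2 ± 1.19 to 4.68 ± 0.63 CPM and STC2 from 38.8 ± 2.54 to 2.35 ± 0.18 CPM. The 6 members that rose, PDIA4, CALR, HYOU1, ERN1, SDF2L1 and HSPA5, are chaperone genes and other genes of the endoplasmic reticulum. PDIA4 and ERN1 lie in raised windows. With the regional offset the median was -0.75 (adjusted p = 2.5e-10).

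NRF2 targets, which serve antioxidant defence, were higher as a group (median 0.31, camera adjusted p = 0.0056), with 11 of 20 members higher and 2 lower. The call did not hold with an estimated correlation (adjusted p = 0.31). NQO1 rose from 33.1 ± 2.18 to 66.2 ± 3.70 CPM (SD, n = 4), GCLC from 34.2 ± 1.10 to 58.6 ± 2.33 CPM and AKR1B1 from 74.0 ± 2.13 to 118.7 ± 9.18 CPM. GCLC and AKR1B1 lie in raised windows, but with the regional offset the list had a median of 0.36, with 12 higher and 2 lower (camera adjusted p = 0.0013). The cystine transporter gene SLC7A11, which is also in the ATF4 list, went the other way, from 220.6 ± 15.4 to 97.7 ± 2.58 CPM.

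p53 targets were lower as a group, with 12 of 23 members lower and 3 higher (median -0.23, camera adjusted p = 0.015, and adjusted p = 0.15 with an estimated correlation). With the regional offset the median was -0.10, with 11 lower and 4 higher (adjusted p = 0.012). SESN2, which is also in the ATF4 list, fell from 78.6 ± 3.07 to 20.98 ± 0.87 CPM (SD, n = 4), the growth arrest gene GADD45A from 15.02 ± 1.43 to 4.08 ± 0.87 CPM and CCNG1 from 329.4 ± 3.36 to 202.8 ± 2.98 CPM, while BTG2, in a raised window of chromosome 1, rose from 27.4 ± 0.66 to 41.3 ± 2.71 CPM.

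Target genes of MLL fusion proteins were lower as a group: 10 of 19 tested members fell and 2 rose (median -0.34, camera adjusted p = 0.020, and adjusted p = 0.17 with an estimated correlation). SENP6 fell from 392.0 ± 10.5 to 151.6 ± 7.21 CPM (SD, n = 4), RUNX2 from 372.9 ± 8.06 to 238.8 ± 4.46 CPM and BCL2, an anti-apoptotic gene, from 306.2 ± 14.7 to 201.5 ± 9.65 CPM, and LAMP5 rose from 46.5 ± 2.38 to 111.8 ± 2.79 CPM. BCL2 lies in a lowered part of chromosome 18, where the other genes of its window had a median of -0.31. RUNX2 lies in a raised window, with neighbours at 0.34, and overlaps SUPT3H. With the regional offset the list of MLL fusion targets had a median of -0.31, with 11 lower and 2 higher (camera adjusted p = 0.011). The list stem and progenitor genes was split, with 7 of 15 higher and 6 lower (median -0.05, adjusted p = 0.70, and 0.0496 without the unnamed loci). Beside KIT, the polycomb gene BMI1 fell from 86.9 ± 1.96 to 40.8 ± 1.17 CPM, the receptor gene FLT3 from 218.0 ± 4.45 to 161.2 ± 3.20 CPM and LMO2 from 145.8 ± 5.74 to 111.4 ± 4.23 CPM. BMI1 and KIT lay outside the shifted windows.

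Monocyte and macrophage markers did not pass as a group (13 of 25 higher, 6 lower, median 0.21, camera adjusted p = 0.11), although single markers moved strongly. Lysozyme (LYZ) rose from 305.5 ± 6.50 to 741.1 ± 13.9 CPM (SD, n = 4), MNDA from 32.2 ± 1.73 to 96.5 ± 2.78 CPM and VCAN from 10.1 ± 0.64 to 43.4 ± 3.95 CPM, while S100A9, a calcium-binding protein gene of mature myeloid cells, fell from 27.1 ± 1.41 to 6.48 ± 0.30 CPM. Without knockout replicate 2 the list monocyte and macrophage markers passed (median 0.23, adjusted p = 0.015), as it did with no filter on low counts (0.032), with DESeq2 (0.0020) and without the unnamed loci (0.044). With the regional offset the median was 0.10 (adjusted p = 0.42), and 9 of the 25 members lie in shifted windows. Camera with an estimated correlation gave adjusted p = 0.45. MNDA, VCAN and S100A9 all lie in raised windows. The list NF-kB and inflammatory cytokine genes fell short of the threshold (2 of 20 higher, 9 lower, median -0.21, adjusted p = 0.067). It passed with the regional offset (adjusted p = 0.030), with no filter on low counts (0.031), with DESeq2 (0.042) and on both FPKM scales (0.028 and 0.026). With an estimated correlation it did not pass camera (adjusted p = 0.26). The adhesion receptor gene ICAM1 fell from 31.6 ± 0.79 to 10.7 ± 0.21 CPM, TNFAIP3 from 239.6 ± 5.51 to 148.2 ± 3.81 CPM, NFKBIZ from 40.1 ± 0.98 to 28.6 ± 2.32 CPM and NFKBIA from 104.7 ± 5.12 to 83.3 ± 4.84 CPM.

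Neighbours of CD36 on chromosome 7 tended lower without passing as a list: 8 of 14 tested genes were lower and 1 higher (median -0.24, camera adjusted p = 0.061). GNAI1, which ends upstream of CD36 at 80226181, fell from 11.95 ± 0.85 to 5.05 ± 0.38 CPM (SD, n = 4), GSAP from 44.8 ± 1.64 to 26.0 ± 0.99 CPM, DMTF1 from 106.2 ± 6.47 to 83.3 ± 5.68 CPM and SEMA3A from 4.78 ± 0.68 to 2.43 ± 0.57 CPM. The list CD36 neighbours on chromosome 7q21 passed with no filter on low counts (adjusted p = 0.012), without knockout replicate 1 and without knockout replicate 4 (adjusted p = 0.043 in each case). It did not pass camera with the regional offset (median -0.20, adjusted p = 0.12) or with an estimated correlation (adjusted p = 0.51).

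Ribosomal protein genes were slightly lower: 30 of 40 fell and 5 rose, with a median of -0.29 (camera adjusted p = 0.00014, but adjusted p = 0.72 with an estimated correlation). The 5 that rose, RPL27, RPL19, RPL23, RPS18 and RPS23, lie in raised windows, and with the regional offset 33 members were lower and 0 higher by edgeR (median -0.27, adjusted p = 2.2e-06). RPL5 fell from 1760 ± 13.4 to 1289 ± 45.7 CPM (SD, n = 4), RPL4 from 2125 ± 41.1 to 1601 ± 62.0 CPM, RPL3 from 2156 ± 42.4 to 1622 ± 86.4 CPM and RPL15 from 1236 ± 38.9 to 933.9 ± 34.0 CPM. Many of these genes have processed pseudogenes that can share reads. Mitochondrially encoded RNA took 6.71% to 8.50% of counts in control and 6.30% to 6.47% in knockout libraries, and the 13 mitochondrial mRNAs did not pass camera as a list (3 higher, 5 lower, adjusted p = 0.87). The 11 tested replication-dependent histone genes, whose mRNAs lack poly(A) tails, did not pass as a list (median 0.55, adjusted p = 0.87).

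Marker lists of other cell types gave no call by camera, while fry called B and plasma cell markers lower (adjusted p = 0.00034) and epithelial and fibroblast markers higher (adjusted p = 0.00024). For T and NK cells 2 of 6 tested markers were higher and 2 lower (camera adjusted p = 0.90), for B and plasma cells 2 of 6 were higher and 2 lower (adjusted p = 0.70), for megakaryocytes and platelets 1 of 8 was higher and 1 lower (adjusted p = 0.71), and for epithelial cells and fibroblasts 2 of 7 were higher and 1 lower (adjusted p = 0.57, median -0.25 and mean 0.38). Of the erythroid and endothelial markers 2 and 4 were expressed enough to test, fewer than the 5 needed for a list test, with 1 and 3 of them higher.

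**Figure D3:**
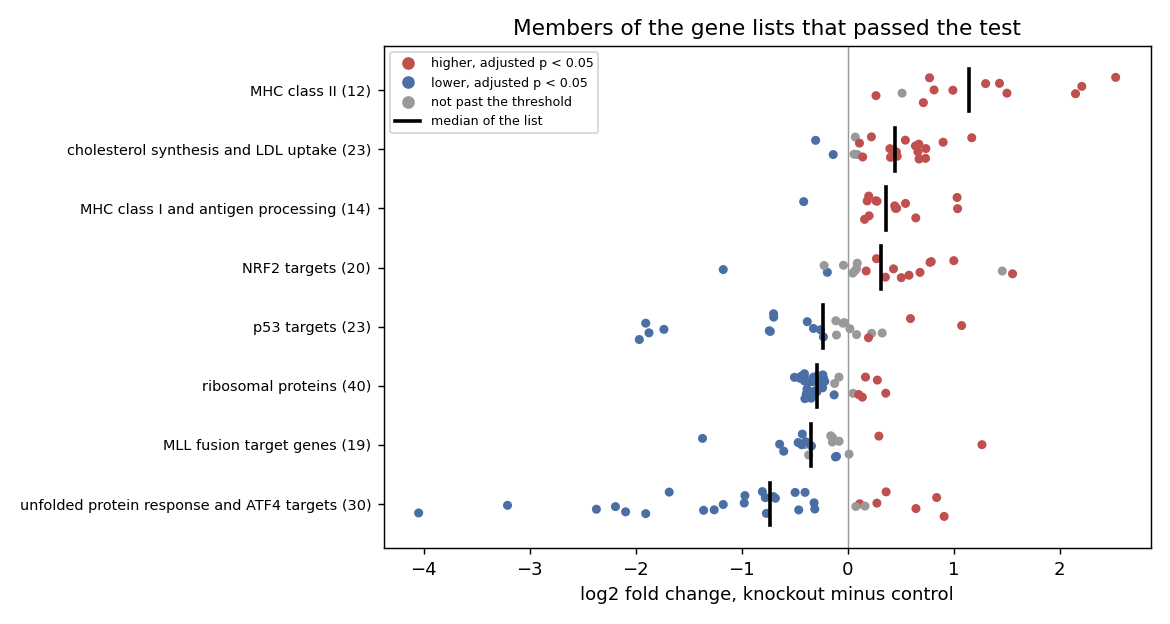
Log2 fold change (knockout minus control, horizontal axis) of each tested member of the 8 gene lists that passed the camera test, with list size in brackets, members past the threshold in red (higher) or blue (lower), others in grey, and the list median as a black bar. Medians run from 1.15 for MHC class II to -0.73 for the unfolded protein response and ATF4 targets.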

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

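The checks for a library that stands apart were fixed by rule before the data were examined, but the MT-RNR1, RN7SL2 and unnamed-loci measures were chosen after the libraries had been seen. In each group of 4 libraries, the gap of the highest or lowest library to its nearest neighbour was divided by the range of the group. That ratio passed Dixon's 95% critical value in 16 of 180 groups tested, against 9 expected by chance.

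Knockout replicate 2 stood apart in 3 library measures. Unnamed loci took 0.732% of its counts, against 0.291% to 0.308% in the other knockout libraries (ratio 0.961). The mitochondrial ribosomal RNA MT-RNR1 stood at 5487 CPM, against 2693 to 3016 CPM (ratio 0.885). The signal recognition particle RNA RN7SL2 stood at 385 CPM, against 33.5 to 56.0 CPM (ratio 0.936). In control replicate 1, RN7SL2 stood at 116 CPM, against 32.1 to 42.7 CPM in the other controls (ratio 0.873).

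CD36 itself was lower in control replicate 2, at 56.7 CPM against 62.3 to 63.3 CPM (ratio 0.851), far above every knockout library. KIT was lower in knockout replicate 3, at 1.22 CPM against 1.97 to 2.07 CPM (ratio 0.877). GNAI1, upstream of CD36, was higher in knockout replicate 1, at 5.62 CPM against 4.81 to 4.90 CPM (ratio 0.888).

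Among lipid genes, DBI was lower in control replicate 3 (67.2 CPM against 76.7 to 78.1 CPM, ratio 0.871), INSIG1 was higher in control replicate 2 (149.4 CPM against 144.8 to 145.2 CPM, ratio 0.901) and AGPAT2 was higher in control replicate 1 (52.9 CPM against 48.4 to 48.8 CPM, ratio 0.902). PSMB9 was lower in control replicate 3 (24.3 CPM against 29.6 to 30.2 CPM, ratio 0.912). MNDA was higher in control replicate 3 (34.8 CPM against 31.1 to 31.7 CPM, ratio 0.830) and in knockout replicate 3 (100.6 CPM against 94.6 to 95.4 CPM, ratio 0.854). BMI1 was lower in control replicate 2 (84.01 CPM against 87.7 to 88.3 CPM, ratio 0.870), NQO1 was higher in control replicate 4 (36.3 CPM against 31.7 to 32.2 CPM, ratio 0.898) and RPL3 was higher in knockout replicate 3 (1750 CPM against 1562 to 1592 CPM, ratio 0.841). Each of these genes kept its direction and its call with that library left out.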

How the results depend on the processing

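The regional offset, the fit without unnamed loci and the 2 other window settings were chosen after the data were seen. CD36 and the other named genes kept direction and call in every alternative that tested them. The count of genes past the threshold lay between 7138 (limma-trend on log2(FPKM + 0.1)) and 9329 (no filter), and was 8167 by DESeq2, 7843 of them shared with edgeR in the same direction. The count of genes past the threshold by at least 2-fold was 2015 with no filter, and with limma-trend 385 on log2(FPKM + 1) and 685 on log2(FPKM + 0.1), where test, unit and filter all differ, so the cause was not tested. With the regional offset 8567 genes passed; 7297 of the 9059 calls were shared in the same direction, 1536 were lost and 226 reversed. No other alternative reversed a call.

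With no filter 15 lists passed (8 higher, 7 lower), and with DESeq2 15 (9 higher). Both settings tested more genes, so lists with fewer than 5 tested genes in the main fit could enter. Why these 2 settings passed more lists was not tested. Of the 37 lists of the main fit, 2 passed with an estimated correlation (1 higher, 1 lower) and 28 with fry (13 higher, 15 lower), which does not compare a list with other genes. Windows of 5 Mb gave 41 higher and 17 lower, from more and smaller windows.

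With each library left out in turn, the genes past the threshold ranged from 8581 to 8942, genes higher in the knockout from 4248 to 4464, genes lower in the knockout from 4333 to 4496, genes past the threshold by at least 2-fold from 1406 to 1431, and CD36 from -2.92 to -2.79. List calls ranged from 8 to 11 (4 to 6 higher, 4 to 6 lower) and windows from 32 to 36 higher and 18 to 23 lower. Replicate numbers did not pair the libraries: same-numbered deviations correlated at -0.06, 0.04, -0.04 and 0.003. With a replicate block 8902 genes passed, 8 lists were called and CD36 stood at -2.85. Depth limits genes near 1 count, 0.068 CPM in the shallowest library.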

Other observations

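The windows, the regional offset and the definition of on-off genes were chosen after results had been seen; the tests were then stated before their values were computed, except that the paired interval of the MHC class I change and the intervals and values per gene for the on-off loci were added after those values were seen.

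Lists on growth and metabolism did not pass camera, although fry, which compares a list with no other genes, called several of them. By camera, 13 of 30 nuclear oxidative phosphorylation genes were higher and 3 lower (median 0.10, adjusted p = 0.14), 12 of 26 glycolysis and hypoxia genes were higher and 6 lower (median 0.13, adjusted p = 0.70), and 16 of 28 MYC target and nucleolar genes were higher and 5 lower (median 0.15, adjusted p = 0.086, and 0.030 with the regional offset). Of 27 S phase genes 11 were higher and 4 lower (median 0.06, adjusted p = 0.086, and 0.030 with the offset), and of 29 G2 and M phase genes 8 were higher and 6 lower (median 0.06, adjusted p = 0.35). Camera with an estimated correlation gave adjusted p = 0.80 for the MYC list and 0.61 for the S phase list. BCL2 family and caspase genes had 6 of 23 higher and 9 lower (median -0.11, adjusted p = 0.46). LXR targets had 3 of 9 higher and 2 lower (median -0.06, adjusted p = 0.87), and PPAR targets 2 of 12 higher and 1 lower (median 0.05, mean -0.004, adjusted p = 0.90).

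Signalling and surface lists were split in direction. Interferon-stimulated genes had 11 of 33 higher and 11 lower (camera adjusted p = 0.87, with a median of 0.06 and a mean of -0.03). Immediate early genes had 7 of 25 higher and 12 lower (median -0.19, adjusted p = 0.072, 0.030 with the offset and 0.61 with an estimated correlation). Adhesion and migration genes had 10 of 26 higher and 12 lower (median -0.12, adjusted p = 0.45), matrix and protease genes 7 of 23 higher and 10 lower (median -0.14, adjusted p = 0.71), and CD36 ligands, partners and other scavenger receptors 7 of 17 higher and 4 lower (median 0.03, adjusted p = 0.91). Src, MAPK and STAT components had 11 of 27 higher and 10 lower (median 0.03, mean -0.04, adjusted p = 0.90), and granulocyte genes 3 of 13 higher and 4 lower (median 0.02, adjusted p = 0.64).

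Long chromosome segments shifted together. A difference in chromosome copy number between the cells of the groups predicts a like shift at every expression level. In the raised windows the median was 0.36 in 629 genes of 5 to 30 CPM (95% interval 0.32 to 0.40) and 0.40 in 1054 genes above 30 CPM (0.37 to 0.42). The 95% intervals here and below come from redrawing genes, list members or on-off loci as if independent. They hold no spread between libraries, and genes of 1 window can move together. Both medians lay above 0.19, the bound stated in advance, so the prediction was met. The windows had been chosen for a high median of these same genes, which made that outcome likely. Any other cause acting on whole regions could meet it too, so it does not single out copy number. No single copy ratio covers the segments. A gain from 3 to 4 copies would give 0.42, from 2 to 3 copies 0.58, and a loss from 2 copies to 1 would give -1. Raised segments had medians of 0.20 to 0.51. Their single windows had medians of 0.14 to 0.61, a range that holds both 0.42 and 0.58. On chromosome 12 the lowered segment from 20 to 50 Mb had a median of -0.72, and its lowest window had -1.45. After correction for GC content and transcript length the median was 0.44, which argues against those biases as the whole cause. RNA alone does not measure copy number, and as the labels do not say whether the knockout cells were 1 clone or a pool, a difference that follows from CD36 loss and one that the cells carried for another reason both stay open.

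The list calls were weighed against the same regional shift. With the offset, MHC class II stayed past the threshold (adjusted p = 2.2e-06), as did cholesterol synthesis (adjusted p = 1.8e-06, median 0.45 to 0.40) and the unfolded protein response and ATF4 targets (adjusted p = 2.5e-10), which argues against the regional shift as their whole cause. For MHC class I the call ended (adjusted p = 0.059), and the median went from 0.36 (95% interval 0.20 to 0.54) to 0.179 (-0.03 to 0.26). That met the condition stated in advance for a regional cause, a lost call and a median under 0.180, by a narrow margin, and the paired change of -0.18 had an interval of -0.37 to 0.02. A regional rise may therefore be a source of this call. A rise of these genes themselves stays open, as the other genes of their windows included members of this list. CD36 loss as the origin of any of these list changes was not tested apart from other differences between the cells.

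In all, 11 loci, IGF2BP1, TRIM32 and PPP1R3A from the largest falls among them, were on in one group and off in the other, with a mean of at least 5 CPM in one and at most 0.5 CPM in every library of the other. With those 3, TP73-AS1, AC097382.2 and AC079466.1 (82.8 to 0.079 CPM) were off in the knockout, and TCAM1P (0.25 to 6.90 CPM) and 4 unnamed loci were on; those outside the named-gene rule were chosen after their values were seen. Loss or gain of a DNA segment of 100 kb or more would move neighbours alike, and 24 neighbours of 6 of these genes had a median signed change of 0.087 (95% interval -0.32 to 0.69), which reaches past 0.5, the bound stated in advance for excluding it. The neighbour changes were not corrected for the regional shift. IGF2BP1 and TCAM1P lie in the raised part of chromosome 17, so their neighbours may carry that rise. The other genes in the window of IGF2BP1 had a median of 0.50. The genes differed: all 4 neighbours of IGF2BP1 went the other way (-1.38 to -0.29), while the 1 neighbour of TRIM32, ASTN2, which overlaps it so that reads could be shared, went from 0.718 CPM to 0 counts in the knockout. A DNA change may therefore be a source for some of these loci, and it stays open. RNA of other cells stays open too: 5 loci have a symbol that a marker list could hold, and 0% of them were in the lists of other cells, which allows up to 52.2%.

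The number of genes past the threshold was tied to the real grouping of the libraries. Of the 35 splits of the 8 libraries into 4 and 4, 1 gave as many genes as the real split. That is the real one with 9059 genes, and the highest of the others gave 1 gene. Every other split mixes control and knockout libraries, so a difference between the groups becomes spread within each part. Such splits call few genes whatever the source of that difference. They therefore cannot exclude a chance difference between the cultures or cells that the groups came from.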
